A study of Arabidopsis thaliana with 18 samples.

How the data were processed

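The data were mRNA levels in whole Arabidopsis thaliana embryos, which per the labels were isolated by hand from plants grown at 22 °C with 16 h of light and 8 h of dark. The labels name 6 stages with 3 libraries each, 18 in all, and the stages with a cell number in their name are called here as the labels call them. Per the labels, mRNA was captured by its poly(A) tail on beads, and cDNA was made and amplified with a kit for very small amounts of RNA. How far this captured plastid and mitochondrial transcripts is not stated, so changes in their TPM need not be changes in their levels. The authors trimmed the reads with Trim Galore 0.6.6 and quantified them with kallisto 0.44.0 against TAIR10, and deposited 1 table of TPM per gene. How transcripts were summed to genes is not stated. Each column summed to 1000000 TPM, so the values are shares of a library, and the sequencing depth and the counting error behind each value are unknown. Some mitochondrial genes carry identical values in every library, so reads shared between copies cannot be assigned to 1 of them.

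Of 27564 genes in the table, 27445 were matched by identifier to the reference annotation for names, and 119 plastid and mitochondrial identifiers were not. That annotation is TAIR10.1 while the authors used TAIR10, so no coordinates are given. Symbols are those of the reference or of the gene lists, each with its identifier at first mention.

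Genes at 1 TPM or more in at least 3 libraries, 18338 in all, were tested. A linear model with 1 mean per stage was fitted to log2(TPM + 1) of all 18 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variances. Each stage was compared with the one before it, and the heart with the 2/4-cell stage. The moderated F test asked which genes vary over the 6 stages. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes are those of the fit, on the scale of TPM + 1, which understates the change of low genes and makes it depend on the pseudocount. Means and SD are of TPM. Nothing states that the replicates come from separate plants, so the p values measure only the spread between these samples.

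The 19 gene lists, with 572 genes, the comparisons, the thresholds and the alternatives planned were set before the data were examined. They cover zygote and early embryo, shoot apex and cotyledon, polarity, root and vascular, and maturation regulators, protoderm and cuticle, auxin, fatty acid synthesis, nuclear photosynthesis, cell cycle, DNA methylation with small RNA and Polycomb, ribosomal proteins, the 26S proteasome, histones H3.1 and H4, endosperm markers, seed coat markers, heat shock and wounding, and plastid-encoded and mitochondrion-encoded genes. Lists were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over all lists and comparisons, and again with the correlation estimated for each list. Of all list calls, those of the shoot list in 32-cell against 16-cell and in heart against 2/4-cell held with the estimated correlation. Summed TPM of a list were compared between stages by an exact permutation test over libraries, two-sided, in which 3 against 3 libraries cannot give a p under 0.1.

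Genes were named by a rule set in advance. It takes the 5 largest rises and falls of each comparison of consecutive stages, and 10 of each for heart against 2/4-cell, among called genes with a symbol, a mean of 10 TPM or more in the higher stage and no overlap between the libraries. From each list it takes up to 4 called members with the largest change and up to 2 uncalled members with the highest mean, and from the 5 lists of regulators any member. YUC4 in 8-cell against 2/4-cell and PDF1, RBCS3B, ATS, GATL5, SBT1.7 and PER36 in heart against 2/4-cell were named outside this rule, after their values were seen.

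The model was tested on simulated data with 200 changed genes among 18338. Each gene's spread was scaled by the mean spread of the stage, and genes varied independently. With equal weights it recovered 76.2% of 4-fold changes in 8-cell against 2/4-cell, but 46.2% of its calls there were false, while in heart against globular it recovered 67.0% with 0 false calls. With library weights 4.94% and 5.18% of the calls were false. Simulated libraries of a stage had the same spread, unlike real ones, and the share of false calls also depends on how many genes change. These shares therefore need not hold for the real calls. The equal weights set in advance were kept for the values reported, and counts with library weights are given beside them.

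Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalization, organelle genes left out, robust moderation, library weights, a block for the replicate number, only the stages compared in the fit, each library left out in turn, the estimated correlation, and limma's fry, which tests a list against no change and not against other genes. Added after the data were seen were the F test without the 2/4-cell stage, heart against 8-cell, removal of a trend with transcript length, lists without members already seen, seed coat markers each against the sum of the others, and the stage of the highest mean under other scalings. The replicate numbers were taken to pair the libraries only if every pair with the same number correlated above 0.1 across genes. Over 45 such pairs the residuals had a mean r of 0.034 (-0.139 to 0.210) and 9 exceeded 0.1, so no pairing was used. The mean over pairs with different numbers was -0.017, which largely follows from the first, since the residuals of a stage sum to 0. Of 18 libraries 12 correlated best with libraries of their own number, more than chance gives on average. Since the rule asked for every pair, a batch shared by libraries of the same number is not excluded. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. No reads were used here, and splicing and alleles were not analysed here.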

Results

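Embryos isolated by hand from Arabidopsis thaliana, the thale cress, were profiled at 6 stages of their early development. The stages were named 2/4-cell, 8-cell, 16-cell, 32-cell, globular and heart, and each had 3 libraries, 18 in all. At the heart stage the cotyledons emerge from the flanks of the embryo. The unit is TPM, a transcript's share of all transcripts in a library, given as mean ± SD over the 3 libraries of a stage (n = 3). Every library summed to 1000000 TPM, so its sequencing depth is unknown and no interval or detection limit was derived. Of 27564 genes, 15381 to 16731 reached 1 TPM in a library, and 5271 to 9283 were listed at 0. The 10 most abundant genes held 4.23% to 9.31% of a library's total.

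Libraries of the 2/4-cell stage were the least alike, with Pearson's r between pairs of libraries of 0.884 to 0.900 over the log2(TPM + 1) of 18338 genes, which are not independent replicates. The range was 0.951 to 0.957 at 8-cell, 0.929 to 0.953 at 16-cell, 0.958 to 0.970 at 32-cell, and 0.968 to 0.981 at both the globular and the heart stage. The first principal component held 46.8% of the variance and ran from -103 to -90.1 in the 2/4-cell libraries to between 88.3 and 100.3 in the heart libraries. On it 16-cell replicate 3 lay at -56.5, among the 8-cell libraries, while the other 16-cell libraries lay at -26.0 and -17.9.

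**Figure D1:**
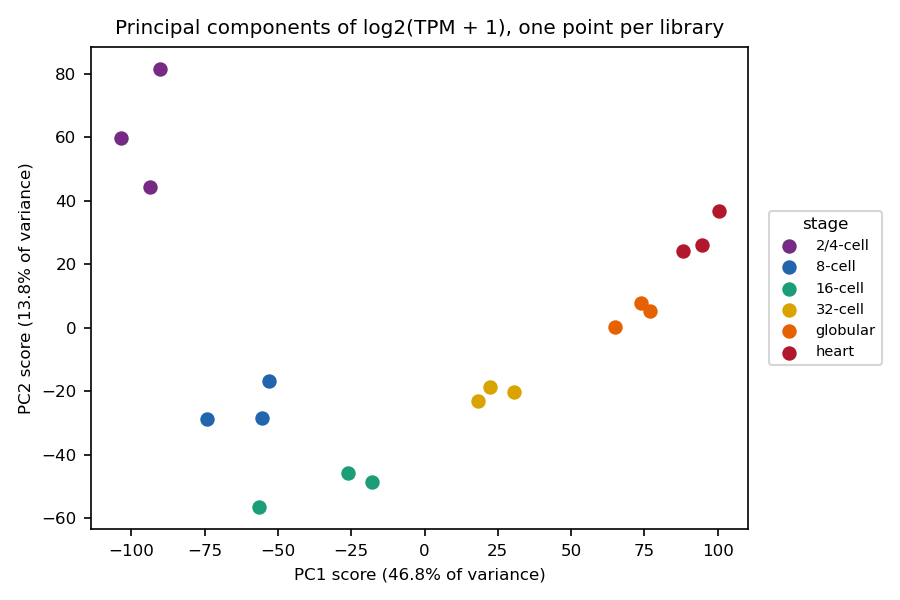
Scores of the 18 libraries on the first (46.8% of variance, x axis) and second (13.8%, y axis) principal components of log2(TPM + 1), 1 point per library, coloured by stage. From left to right the stages follow each other from 2/4-cell (-103 to -90.1) to heart (88.3 to 100.3), with 16-cell replicate 3 at -56.5.

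Which genes vary at all over the course was asked with a moderated F test. Of 18338 genes tested, 9003 (49.1%) passed, and 4477 genes (49.7% of them) had their highest mean log2(TPM + 1) at the heart stage. The 2/4-cell stage held the highest mean of 1716 genes, the globular stage of 1067, the 32-cell stage of 817, the 8-cell stage of 513 and the 16-cell stage of 413. This order depended on the scaling, as tests added after the data were seen showed. Under median-ratio scaling 2448 of 8012 varying genes had their highest mean at 2/4-cell and 2201 at heart, and under quantile normalization 2163 and 2100 of 7573. Single regulators followed separate courses. WOX2 (AT5G59340), a homeobox gene of the apical cell lineage, stood at 137 ± 10.9 TPM at the 2/4-cell stage and 19.3 ± 3.76 at the heart stage. TMO5 (AT3G25710), a vascular regulator, stood at 0.695 ± 0.0866 TPM at the 2/4-cell stage and 49.3 ± 9.01 by the 8-cell stage. CUC1 (AT3G15170), which sets the boundary between the cotyledons, reached 40.1 ± 6.9 TPM at the 32-cell stage after 2.71 ± 2.05 at the 16-cell stage. STM (AT1G62360), needed for the shoot meristem, went from 4.21 ± 2.76 TPM at the 32-cell stage through 29.9 ± 7.75 at the globular to 89.2 ± 11 at the heart stage. Without the 2/4-cell libraries, an alternative chosen after the data were seen, 8281 genes passed the F test.

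**Figure D2:**
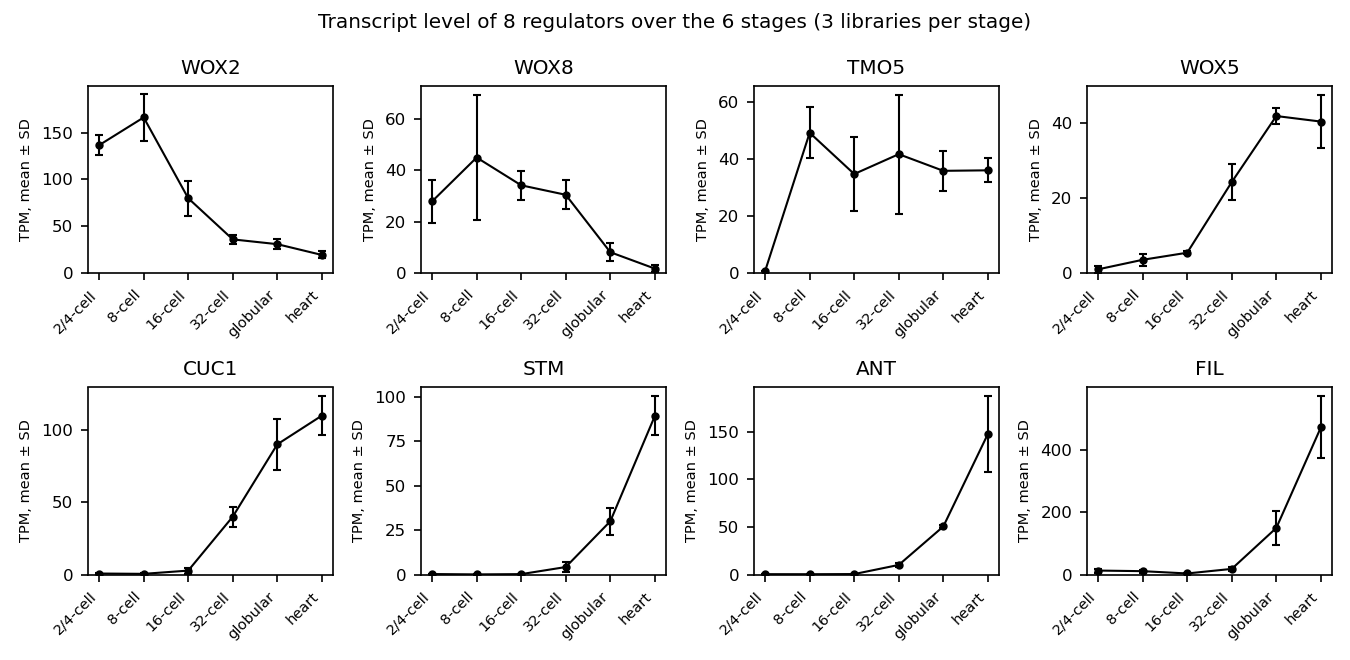
Mean TPM (y axis, linear scale) of 8 regulators at the 6 stages (x axis), points means and bars SD over 3 libraries. WOX2 falls from 137 ± 10.9 TPM at 2/4-cell to 19.3 ± 3.76 at heart, TMO5 goes from 0.695 ± 0.0866 at 2/4-cell to 49.3 ± 9.01 at 8-cell and 36.1 ± 4.27 at heart, and STM, ANT and FIL climb to 89.2 ± 11, 148 ± 39.5 and 472 ± 99.5 TPM at heart.

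Counts of called genes differed with how the spread was modelled, and the libraries of the early stages varied more. The spread within a stage, relative to the mean of the 6 stages, was 1.57 at 2/4-cell, 1.04 at 8-cell, 1.23 at 16-cell, 0.797 at 32-cell, 0.677 at globular and 0.682 at heart, while the limma fit gave all libraries equal weight. Counts with library weights, which let precise libraries count for more, therefore stand beside those with equal weights. The weights ran from 0.266 in 16-cell replicate 3 to 5.53 in globular replicate 3. The other globular libraries had 1.26 and 1.65, and heart replicate 3 had 4.87 against 0.938 and 2.23. Weighted results for the globular and heart stages thus lean on these replicates. TPM are shares of a fixed total, and the median log2 change over all tested genes was 0.46 from 2/4-cell to heart, 0.24 from 16-cell to 32-cell and 0.13 from 32-cell to globular. Under median-ratio scaling, which centres the libraries on their common genes, these medians were 0.03, 0.03 and -0.02.

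**Figure D3:**
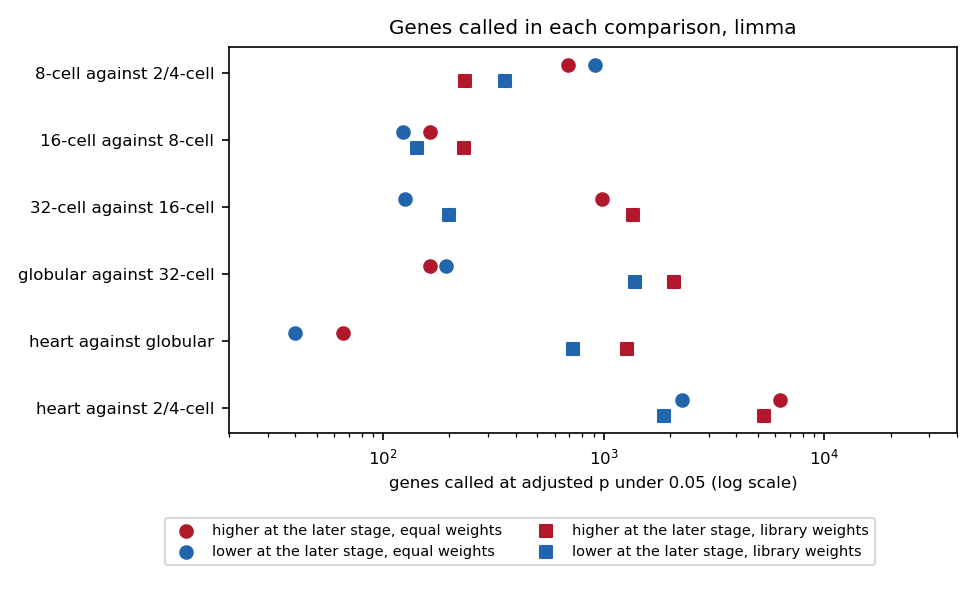
Genes called by limma at an adjusted p under 0.05 (x axis, log scale) in the 6 comparisons (y axis), red higher and blue lower at the later stage, circles with equal weights and squares with library weights. Library weights lower the total from 1608 to 592 for 8-cell against 2/4-cell and raise it from 355 to 3465 for globular against 32-cell and from 106 to 2005 for heart against globular.

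From the 2/4-cell to the 8-cell stage TMO5 rose 29.4-fold, from 0.695 ± 0.0866 to 49.3 ± 9.01 TPM (limma adjusted p = 1.1e-08). ZPR3 (AT3G52770), a small inhibitor of HD-ZIP III transcription factors, rose 22.9-fold from 4.2 ± 1.8 to 115 ± 16.9 TPM, and the calmodulin-like gene CML11 (AT3G22930) rose 19.7-fold from 1.17 ± 1.05 to 38.6 ± 4.09 TPM. The cytokinin response regulators RR5 (AT3G48100) and ARR7 (AT1G19050) rose 11.7-fold to 13.6 ± 3.81 and 6.89-fold to 7.53 ± 1.03 TPM, and the auxin influx carrier LAX2 (AT2G21050) rose 8.41-fold to 28.3 ± 8.58 TPM. The RALF-like peptide genes RALFL9 (AT1G61566), RALFL8 (AT1G61563) and RALFL15 (AT2G22055) fell from 215 ± 144 to 1 ± 0.55 TPM, from 307 ± 201 to 2.03 ± 0.583 TPM and from 101 ± 60.5 to 0.647 ± 0.436 TPM, that is 85.9-, 83.1- and 52.1-fold. AGP23 (AT3G57690), an arabinogalactan protein gene, fell from 134 ± 74.6 to 1.81 ± 0.947 TPM, and TPX2 (AT1G65970), here a thioredoxin-dependent peroxidase gene, from 232 ± 179 to 3.68 ± 0.915 TPM.

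Of 24 tested root, hypophysis and vascular regulators 7 rose and 0 fell, or 8 called when adjusted over the list alone (camera adjusted p = 6.2e-04, adjusted p = 0.191 with an estimated correlation). They included TMO3 (AT4G23750) (4.69 ± 3.61 to 21.4 ± 5.97 TPM) and the root stem cell gene PLT1 (AT3G20840) (20.9 ± 4.05 to 77.8 ± 15.7 TPM). Of 10 polarity regulators, ATHB8 (AT4G32880), REV (AT5G60690) and PHB (AT2G34710), all HD-ZIP III genes, rose 8.29-, 3.43- and 2.88-fold, to 12.6 ± 1.98, 56.4 ± 17.9 and 92.3 ± 6.81 TPM. Also 3 were called when adjusted over the list alone (camera adjusted p = 0.00322, adjusted p = 0.209 with an estimated correlation). Of 36 auxin genes 6 rose and 1 fell, 8 when adjusted over the list alone (camera adjusted p = 0.00938, adjusted p = 0.426 with an estimated correlation). The repressor gene IAA18 (AT1G51950) rose from 19.7 ± 7.19 to 119 ± 14 TPM. The member that fell was YUC4 (AT5G11320), from 99.4 ± 1.84 to 55.3 ± 6.04 TPM, whose call was lost with library weights (adjusted p = 0.136) and without 8-cell replicate 2 (adjusted p = 0.071). Of 22 protoderm and cuticle genes 4 rose and 2 fell, 7 when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.119). PDF1 (AT2G42840), a marker of the outer cell layer, rose from 376 ± 82.1 to 1329.8 ± 414 TPM.

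In the same comparison 12 of 21 tested seed coat markers fell and 0 rose, 16 when adjusted over the list alone (median log2 change -2.0; camera adjusted p = 6.9e-13, adjusted p = 0.0769 with an estimated correlation). They include flavonoid enzymes of the seed coat pigment pathway: TT3 (AT5G42800) fell from 168 ± 132 to 7.47 ± 4.87 TPM, BAN (AT1G61720) from 204 ± 133 to 10.9 ± 2.12 TPM and TT5 (AT3G55120) from 40.1 ± 22.3 to 1.78 ± 1.01 TPM. Nuclear photosynthesis genes moved with them, 16 of 46 falling and 22 when adjusted over the list alone (median -1.22; camera adjusted p = 9.7e-12, adjusted p = 0.303 with an estimated correlation). RBCS1A (AT1G67090) fell from 133 ± 149 to 7.84 ± 5.22 TPM. The summed TPM of that list was 226, 372 and 1324 in 2/4-cell replicates 1, 2 and 3. At 8-cell it was 90.7 to 275, so 2/4-cell replicate 1 lay below 8-cell replicate 3. Of 30 mitochondrion-encoded genes 6 fell and 17 when adjusted over the list alone (median -1.29; camera adjusted p = 4.9e-07, adjusted p = 0.155 with an estimated correlation). Of 17 heat shock and wounding genes 1 fell, and 1 when adjusted over the list alone, the jasmonate enzyme gene LOX2 (AT3G45140), from 18.3 ± 20.2 to 0.672 ± 0.835 TPM. With library weights 8 seed coat markers, 11 nuclear photosynthesis genes, 0 mitochondrion-encoded genes and 1 heat shock or wounding gene fell. By the same weights 4 root, 3 polarity, 5 auxin and 3 protoderm genes rose and none of these lists had a fall. Of 19 lists, 11 passed camera and 0 did so with an estimated correlation.

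With limma, 1608 genes differed between the 8-cell and 2/4-cell stages, 691 higher and 917 lower at 8-cell, and 592 of them, all in the same direction, were also called with library weights, which called no others. In 3385 genes (18.5%) the libraries of these stages did not overlap, where chance gives 10% if the libraries are exchangeable, alike in spread and level. Unequal spread between stages, or a shift of TPM over all genes, can raise that share above 10% in any of the comparisons. With a pseudocount of 0.1 there were 842 higher and 823 lower. The count fell to 954 without 8-cell replicate 1 and to 67 with only these stages in the fit. Simulated data had the spread of the stages and 200 changed genes. There 46.2% of the genes called with equal weights were unchanged, against 4.94% with library weights. The share depends on how many genes change, so it is no estimate for the 1608 calls.

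From the 8-cell to the 16-cell stage single regulators of organ boundaries, polarity and auxin synthesis rose. CUC2 (AT5G53950), a partner of CUC1, rose 7.49-fold, from 2.78 ± 1.51 to 27 ± 10.5 TPM (limma adjusted p = 5.7e-05), and the shoot regulator AIL6 (AT5G10510) 4.41-fold, from 2.96 ± 1.13 to 19.2 ± 15.2 TPM. The abaxial regulators KAN2 (AT1G32240) and KAN1 (AT5G16560) rose from 0.625 ± 0.532 to 9.66 ± 2.48 TPM and from 0.203 ± 0.0311 to 3.19 ± 1.13 TPM. The auxin synthesis gene YUC3 (AT1G04610) rose 6.23-fold to 13.3 ± 2.35 TPM and the auxin efflux carrier PIN4 (AT2G01420) 5.01-fold to 12.8 ± 2.1 TPM. The remaining largest rises were those of the aquaporin gene PIP2;8 (AT2G16850) (9.6-fold, to 18.8 ± 19.2 TPM), MCT1 (AT1G37140) (8.35-fold, to 28.9 ± 14.8), NPY4 (AT2G23050) (7.49-fold, to 28.7 ± 16.3) and MLP28 (AT1G70830) (7.26-fold, to 49.3 ± 24.8). BEN1 (AT2G45400), a gene of brassinosteroid metabolism, fell 3.43-fold, from 398 ± 106 to 119 ± 50.2 TPM (adjusted p = 0.00156).

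The other large falls kept their direction but not their call when single libraries were left out. RBK1 (AT5G10520) fell 5.41-fold but was not called without 8-cell replicates 1 or 3 or 16-cell replicates 2 or 3 (adjusted p up to 0.105). GILT (AT4G12960) fell 4.65-fold but was not called without 8-cell replicates 2 or 3 or 16-cell replicates 1 or 2 (up to 0.108). MS2 (AT3G03780) fell 4.22-fold but was not called without 8-cell replicates 1 or 3 or 16-cell replicates 2 or 3 (up to 0.136). The auxin-induced gene IAA1 (AT4G14560) fell 3.64-fold but was not called without 8-cell replicates 1, 2 or 3 or 16-cell replicates 1 or 2 (up to 0.115). WOX2 fell from 166 ± 24.8 to 80 ± 18.7 TPM, a call lost without 8-cell replicate 1 or 16-cell replicate 2 (adjusted p up to 0.0686).

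Of 24 root and vascular regulators 3 rose and 2 fell, 7 when adjusted over the list alone (camera adjusted p = 0.0375, adjusted p = 0.434 with an estimated correlation). JKD (AT5G03150) and WIP4 (AT3G20880), root zinc finger genes, rose to 4.38 ± 1.42 and 9.7 ± 3.81 TPM, and the cytokinin-activating gene LOG4 (AT3G53450) fell from 86.1 ± 35.8 to 26.1 ± 6.65 TPM. The list's call was lost without 8-cell replicate 2 (adjusted p = 0.0597), 8-cell replicate 3 (0.0678), 16-cell replicate 2 (0.0812) or 32-cell replicate 2 (0.0515). Among polarity regulators 3 of 10 rose, 6 when adjusted over the list alone, although the list's median was -0.33, of opposite sign to its test, which it did not pass (adjusted p = 0.705). Of 30 mitochondrion-encoded genes 6 fell, 9 when adjusted over the list alone (median -1.14; camera adjusted p = 2.8e-06, adjusted p = 0.168 with an estimated correlation). Heat shock and wounding genes had a median log2 change of -0.94 (camera adjusted p = 3.1e-06, adjusted p = 0.259 with an estimated correlation), with 1 of 17 called lower and 5 when adjusted over the list alone. With library weights 4 root regulators rose and 2 fell, 3 polarity regulators rose, and 6 mitochondrion-encoded and 1 heat shock or wounding gene fell.

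Limma called 286 genes, 163 higher and 123 lower at 16-cell, and library weights 375, with 251 genes called by both. In 2532 genes (13.8%) the libraries did not overlap, where exchangeable libraries give 10%. The count was 108 without 16-cell replicate 2, 154 without 8-cell replicate 2 and 237 without 16-cell replicate 3, and 0 with only these stages in the fit, where 1675 genes had an unadjusted p under 0.05.

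From the 16-cell to the 32-cell stage DRNL (AT1G24590), a cotyledon regulator, rose 26.3-fold, from 2.5 ± 2.41 to 80.6 ± 23 TPM (limma adjusted p = 4.7e-07), CUC1 12-fold, from 2.71 ± 2.05 to 40.1 ± 6.9 TPM, and CUC3 (AT1G76420) 6.38-fold, from 4.61 ± 2.05 to 33.7 ± 6.77 TPM. ANT (AT4G37750), a growth regulator of lateral organs, rose from 0.472 ± 0.222 to 10.1 ± 1.96 TPM and STM from 0.22 ± 0.117 to 4.21 ± 2.76 TPM. Of 19 tested shoot apex and cotyledon regulators 8 rose and 0 fell, also 8 when adjusted over the list alone. Its median log2 change was 0.61 against 0.24 for all genes (camera adjusted p = 5.8e-06, adjusted p = 0.0333 with an estimated correlation). The list held its call with that correlation, as none of the other 18 fixed lists did between consecutive stages.

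HP6 (AT1G80100), a cytokinin signalling inhibitor, rose 16.2-fold, from 3.48 ± 2.77 to 66.2 ± 23.3 TPM, and the clock gene LHY (AT1G01060) 14.5-fold, from 1.12 ± 0.585 to 29.2 ± 4.8 TPM (adjusted p = 9.7e-07). LCR22 (AT4G29280), a gene for a small cysteine-rich protein, was listed at 0 in all 3 16-cell libraries and stood at 18 ± 15.6 TPM at 32-cell (adjusted p = 0.00269). LCR35 (AT2G22121) of the same family rose from 4.72 ± 6.98 to 82.9 ± 79.2 TPM, a call lost without 16-cell replicates 1 or 2 or 32-cell replicates 1 or 3 (adjusted p up to 0.121). CAM8 (AT4G14640), a calmodulin-like gene, fell 8.36-fold, from 17.5 ± 5.4 to 1.27 ± 0.888 TPM, CLPS5 (AT5G39930) 3.58-fold to 13.7 ± 3.78 TPM and ENODL16 (AT3G01070) 3.38-fold to 19.8 ± 3.0 TPM. PAL3 (AT5G04230) and COBL6 (AT1G09790) fell 3.74- and 3.4-fold, and both calls were lost without 16-cell replicate 1 or 32-cell replicates 1 or 2 (adjusted p up to 0.109 and 0.0886). WOX2 fell 2.16-fold, from 80 ± 18.7 to 36 ± 4.55 TPM.

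Members of the polarity, root, photosynthesis and fatty acid lists rose as well. Of 10 polarity regulators 5 rose, also 5 when adjusted over the list alone, among them the abaxial gene FIL (AT2G45190) (4.7-fold) and the adaxial gene PHV (AT1G30490) (4.3-fold; camera adjusted p = 0.0022, adjusted p = 0.191 with an estimated correlation). Under quantile normalization 3 polarity regulators rose. Of 24 root and vascular regulators 5 rose and 2 fell, 11 when adjusted over the list alone. WOX5 (AT3G11260), a marker of the root quiescent centre, rose from 5.33 ± 0.433 to 24.2 ± 4.72 TPM, HSFB4 (AT1G46264) from 0.34 ± 0.201 to 12.6 ± 3.6 TPM and SCR (AT3G54220), which patterns the root ground tissue, from 16.2 ± 6.58 to 47.2 ± 9.76 TPM. That list's call (camera adjusted p = 0.0337, adjusted p = 0.426 with an estimated correlation) was lost without 16-cell replicate 1 (adjusted p = 0.112), 16-cell replicate 3 (0.0551) or 32-cell replicate 2 (0.0667). Of 46 nuclear photosynthesis genes 22 rose and 0 fell, 35 when adjusted over the list alone (median 1.76; camera adjusted p = 5.9e-16, adjusted p = 0.218 with an estimated correlation). RBCS1A rose from 11.6 ± 2.78 to 133 ± 52.2 TPM and the plastocyanin gene PETE2 (AT1G20340) from 1.6 ± 0.493 to 20.8 ± 4.89 TPM. Of 28 fatty acid genes 3 rose, 9 when adjusted over the list alone (camera adjusted p = 7.6e-04, adjusted p = 0.413 with an estimated correlation). ACP4 (AT4G25050) rose from 5.22 ± 3.3 to 31.6 ± 4.02 TPM.

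Of 21 seed coat markers 4 rose and 5 when adjusted over the list alone (median 1.04; camera adjusted p = 0.00345, adjusted p = 0.367 with an estimated correlation). TT5 rose from 0.428 ± 0.165 to 9.77 ± 4.4 TPM and F3H (AT3G51240) from 4.74 ± 0.686 to 30.8 ± 9.08 TPM. The list was lost without 32-cell replicate 2 (adjusted p = 0.0838), whose seed coat sum was 433 TPM against 188 and 199.8 in the other 32-cell libraries. Under median-ratio scaling and under quantile normalization 2 seed coat markers rose (medians 0.98 and 0.64). Ribosomal protein genes had 0 members called and a median of -0.21 (camera adjusted p = 4.8e-10, adjusted p = 0.119 with an estimated correlation). Under median-ratio scaling their median was -0.47 and 1 fell, and under quantile normalization it was -0.02 and the list was not called (adjusted p = 0.820). With library weights 8 shoot, 4 polarity and 5 root regulators, 31 nuclear photosynthesis genes, 6 fatty acid genes and 3 seed coat markers rose and 2 root regulators fell. Of 19 lists, 13 passed camera and 1, the shoot list, with an estimated correlation.

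Limma called 1111 genes, 985 higher (88.7%) and 126 lower at 32-cell, and library weights 1558, with 1025 called by both. Higher genes were 68.2% of the calls under median-ratio scaling and 62.8% of 736 calls under quantile normalization, which kept 729 and 579 of the 1111 calls. With a trend with transcript length removed, an alternative chosen after the data were seen that also centres the libraries, 613 were higher (54.4%) and 513 lower, and 738 of the 1111 calls were kept. The count was 550 without 32-cell replicate 1, 682 without 32-cell replicate 2, 696 without 16-cell replicate 3, 703 without 32-cell replicate 3 and 659 with only these stages in the fit. In 4666 genes (25.4%) the libraries did not overlap, where exchangeable libraries give 10%.

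From the 32-cell to the globular stage NSP5 (AT5G48180), which acts in glucosinolate breakdown, rose 26.9-fold, from 0.964 ± 0.43 to 58.4 ± 33.2 TPM (limma adjusted p = 3.3e-05). The sulfur deficiency genes ATSDI1 (AT5G48850) and LSU1 (AT3G49580) rose from 4.69 ± 0.788 to 124 ± 38.6 TPM and from 0.316 ± 0.149 to 18.9 ± 10.5 TPM, and MSRB5 (AT4G04830), a methionine sulfoxide reductase gene, from 0.663 ± 0.572 to 18.5 ± 13.3 TPM. STM rose 6.48-fold, from 4.21 ± 2.76 to 29.9 ± 7.75 TPM, ANT 4.69-fold, from 10.1 ± 1.96 to 50.4 ± 1.42 TPM, and FIL 7.89-fold, from 18 ± 6.0 to 149 ± 55.1 TPM. OFP14 (AT1G79960) went from 31.5 ± 8.81 TPM to being listed at 0 in all 3 globular libraries (adjusted p = 1.2e-04).

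The other large falls were of small cysteine-rich protein genes and of CYP81D2 (AT4G37360), a cytochrome P450 gene. LCR36 (AT4G09153) fell 10.8-fold, from 17.5 ± 15 to 0.26 ± 0.45 TPM (adjusted p = 0.0088). LCR22 fell 9.76-fold but was not called without 32-cell replicates 1 or 3 or globular replicates 2 or 3 (adjusted p up to 0.108). LCR23 (AT4G29273) fell 8.71-fold but was not called without 8-cell replicate 3, 16-cell replicates 1, 2 or 3, 32-cell replicates 1, 2 or 3, globular replicates 1, 2 or 3 or heart replicate 1 (up to 0.254). CYP81D2 fell 8.41-fold but was not called without 32-cell replicate 1 or globular replicates 1 or 2 (up to 0.0717). The suspensor gene WOX8 (AT5G45980) fell from 30.4 ± 5.61 to 8.1 ± 3.57 TPM, a call lost without 32-cell replicates 1 or 2 or globular replicates 1 or 2 (up to 0.131).

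Of 46 nuclear photosynthesis genes 13 rose and 0 fell, 33 when adjusted over the list alone (median 1.53; camera adjusted p = 5.5e-21, adjusted p = 0.168 with an estimated correlation). The photosystem I gene PSAL (AT4G12800) rose from 5.4 ± 3.09 to 47.1 ± 4.41 TPM. Of 87 plastid-encoded genes 18 rose and 0 fell, 57 when adjusted over the list alone (median 1.55; camera adjusted p = 2.0e-24, adjusted p = 0.12 with an estimated correlation). Of 19 shoot regulators 4 rose, 6 when adjusted over the list alone, and 2 under median-ratio scaling (camera adjusted p = 8.1e-04, adjusted p = 0.106 with an estimated correlation). Fatty acid genes had 0 members called and 5 when adjusted over the list alone, with a median of 0.43 (camera adjusted p = 1.7e-04, adjusted p = 0.34 with an estimated correlation). Of 14 zygote and early embryo regulators 2 fell, also 2 when adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.153 with an estimated correlation). Among root regulators MGP (AT1G03840) rose from 1.08 ± 0.446 to 9.6 ± 2.66 TPM, and the list did not pass (adjusted p = 0.268). Auxin genes had a median of 0.15, of opposite sign to their test (adjusted p = 0.645) and -0.01 under median-ratio scaling, with 3 of 36 called lower. Heat shock and wounding genes had a median of -0.98 and 0 called, 3 when adjusted over the list alone (camera adjusted p = 3.4e-08, adjusted p = 0.191 with an estimated correlation). With library weights 39 nuclear photosynthesis and 12 fatty acid genes rose, and 58 plastid-encoded genes rose and 2 fell. By the same weights 7 shoot regulators rose and 1 fell, 4 auxin genes rose and 5 fell, 5 root regulators rose and 2 fell, 1 zygote regulator rose and 2 fell, and 10 heat shock and wounding genes fell.

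Limma called 355 genes, 163 higher (45.9%) and 192 lower at globular, all of them among the 3465 called with library weights, of which 60.1% were higher. Under median-ratio scaling 31.4% of the calls were higher, and with only these stages in the fit 65.9%. The count was 131 without globular replicate 2, 135 without globular replicate 1, 142 without 32-cell replicate 2, 156 without 32-cell replicate 1 and 195 without 32-cell replicate 3, and 1501 with only these stages in the fit. In 6548 genes (35.7%) the libraries did not overlap, where exchangeable libraries give 10%.

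Between the globular and heart stages JAG (AT1G68480), which promotes blade growth, rose 6.96-fold, from 1.97 ± 1.57 to 19.2 ± 8.13 TPM (limma adjusted p = 0.00226), and BOP2 (AT2G41370), a regulator of organ boundaries, 6.27-fold, from 1.66 ± 0.717 to 16 ± 5.74 TPM (adjusted p = 2.6e-04). LTP3 (AT5G59320), a lipid transfer protein gene, fell 3.96-fold, from 3344 ± 521 to 846 ± 157 TPM (adjusted p = 3.8e-05), and LCR68 (AT2G02130), a defensin-like gene, 4.86-fold, from 102 ± 32 to 21.1 ± 10.4 TPM. WOX3 (AT2G28610), a marginal lateral organ gene, rose from 4.14 ± 0.339 to 24.9 ± 5.34 TPM, a call lost without globular replicates 2 or 3 or heart replicates 1 or 3 (adjusted p up to 0.0928). GSTU20 (AT1G78370) rose 5.79-fold but was not called without globular replicates 1 or 3 or heart replicates 1 or 3 (up to 0.123). BCAT-1 (AT1G10060) rose 5.27-fold but was not called without globular replicates 2 or 3 or heart replicates 1 or 3 (up to 0.111). LCR48 (AT3G48231) fell 9.7-fold, from 591 ± 466 to 51.7 ± 27.6 TPM, a call lost without globular replicate 3 or heart replicate 3 (up to 0.0561). SCRL26 (AT4G22105) fell 6.3-fold, lost without globular replicates 2 or 3 or heart replicate 3 (up to 0.16), and MEE26 (AT2G34870) 4.29-fold, lost without globular replicate 3 (0.0551).

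With equal weights few list members were called. Of 19 shoot regulators 3 rose, BOP2, WOX3 and ANT, 6 when adjusted over the list alone. Their median was 0.04 and turned to -0.04 under median-ratio scaling and -0.02 under quantile normalization (camera adjusted p = 0.00347, adjusted p = 0.119 with an estimated correlation). ANT rose from 50.4 ± 1.42 to 148 ± 39.5 TPM, a call lost without globular replicates 1, 2 or 3 or heart replicates 1 or 3 (adjusted p up to 0.176). Of 10 polarity regulators AS1 (AT2G37630) rose from 15.2 ± 5.45 to 61.3 ± 16.1 TPM, lost without globular replicates 2 or 3 or heart replicates 1 or 3 (up to 0.0961). On the list 3 were called when adjusted over the list alone (camera adjusted p = 0.00158, adjusted p = 0.191 with an estimated correlation). Of 46 nuclear photosynthesis genes 2 rose, 20 when adjusted over the list alone. Their median was 1.15 against 0.08 for all genes (camera adjusted p = 4.3e-30, adjusted p = 0.119 with an estimated correlation). The light-harvesting gene LHCB2.3 (AT3G27690) was one of them, from 0.0756 ± 0.131 to 2.28 ± 0.557 TPM. Mitochondrion-encoded genes had a median of 0.92 and 0 called, also 0 when adjusted over the list alone (camera adjusted p = 9.6e-09, adjusted p = 0.119 with an estimated correlation). Their summed TPM was 4304, 2705 and 1650 in heart replicates 1, 2 and 3, and 1138 to 1565 in the globular libraries. Fatty acid genes had a median of 0.32 and 0 called either way (camera adjusted p = 9.5e-06, adjusted p = 0.259 with an estimated correlation). Of 14 zygote regulators WOX8 fell, from 8.1 ± 3.57 to 1.71 ± 1.23 TPM, a call lost without 2/4-cell replicate 2, 8-cell replicates 1 or 2, 16-cell replicates 1, 2 or 3, 32-cell replicates 1, 2 or 3, globular replicates 1, 2 or 3 or heart replicates 1, 2 or 3 (up to 0.362). On the list 2 were called when adjusted over the list alone (camera adjusted p = 1.7e-04, adjusted p = 0.0615 with an estimated correlation). Heat shock and wounding genes had a median of -0.64, 0 called and 2 when adjusted over the list alone (camera adjusted p = 7.5e-10, adjusted p = 0.168 with an estimated correlation). With library weights 41 nuclear photosynthesis genes, 7 fatty acid genes, 5 mitochondrion-encoded genes and 3 polarity regulators rose. By the same weights 7 shoot regulators rose and 2 fell, and 3 zygote regulators and 4 heat shock and wounding genes fell.

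Limma called 106 genes, 66 higher (62.3%) and 40 lower at heart, all of them among the 2005 called with library weights. Which direction had more calls depended on the processing. Of the calls 51.1% were higher under median-ratio scaling, 43.8% under quantile normalization and 47.5% with the length trend removed. With a pseudocount of 0.1 there were 15 higher and 32 lower, with 5 there were 136 and 33, without a filter 178 and 41, and with a filter of 5 TPM 29 and 33. The count was 31 without globular replicate 3, 35 without heart replicate 3, 46 without heart replicate 1 and 56 without globular replicate 2. In 3613 genes (19.7%) the libraries did not overlap, where exchangeable libraries give 10%.

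Across the whole course, from 2/4-cell to heart, the growth regulator gene GRF5 (AT3G13960) rose 109.9-fold, from 0.379 ± 0.0616 to 153 ± 34 TPM (limma adjusted p = 7.7e-12), ANT 107-fold, from 0.364 ± 0.158 to 148 ± 39.5 TPM, and AN3 (AT5G28640), a coactivator of GRF proteins, 84.9-fold, from 3.82 ± 2.64 to 375 ± 49.4 TPM. These folds depended on the pseudocount: with 0.1 and 5 in place of 1 the log2 change of GRF5 was 8.30 and 4.85. STM rose 71.3-fold to 89.2 ± 11 TPM, DRNL 70.6-fold to 176 ± 41.4 TPM and CUC1 66.6-fold to 110.1 ± 13.3 TPM. The sulfate transporter gene SULTR1;2 (AT1G78000), the sugar transporter gene SWEET9 (AT2G39060), the polarity gene YAB5 (AT2G26580) and the bZIP gene PAN (AT1G68640) rose 74.1-, 66.2-, 65.2- and 61.6-fold, to 96.6 ± 19.6, 290.5 ± 47.5, 87.2 ± 8.54 and 167 ± 10.4 TPM. THI2.1 (AT1G72260), a thionin gene, fell 309-fold, from 1121 ± 577 to 2.6 ± 2.23 TPM (adjusted p = 9.2e-10), and LTP6 (AT3G08770) 91.1-fold, from 3015 ± 1708 to 28 ± 7.7 TPM. MLP423 (AT1G24020), COBL6, LCR68, RALFL18 (AT2G33130), RALFL8 and BGLU18 (AT1G52400) fell 93.8-, 78.1-, 58.3-, 57.2-, 56.4- and 56.3-fold. The flavonoid genes BAN and TT4 (AT5G13930) fell 71.6- and 66.8-fold, to 1.42 ± 0.407 and 3.62 ± 0.618 TPM.

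Most shoot, polarity and root regulators rose over the course. Of 19 shoot regulators 16 rose and 2 fell, 19 when adjusted over the list alone, with a median log2 change of 2.46 against 0.46 for all genes (camera adjusted p = 4.3e-06, adjusted p = 0.0333 with an estimated correlation), a call held with that correlation. CUC2 rose from 1.17 ± 0.278 to 81.2 ± 5.29 TPM. The members that fell were DRN (AT1G12980), from 113 ± 30.4 to 18.6 ± 10.9 TPM, and HAN (AT3G50870), whose call was lost without 2/4-cell replicates 1 or 3 or heart replicate 1 (adjusted p up to 0.133) and with library weights (0.0728). Of 10 polarity regulators 9 rose and 0 fell, also 9 when adjusted over the list alone (median 2.82; camera adjusted p = 8.1e-06, adjusted p = 0.119 with an estimated correlation). FIL rose from 12.7 ± 6.56 to 472 ± 99.5 TPM, KAN2 from 0.424 ± 0.183 to 39.7 ± 5.84 TPM and AS1 from 6.7 ± 3.06 to 61.3 ± 16.1 TPM. CNA (AT1G52150) stood at 26 ± 10.5 and 38.8 ± 5.57 TPM and was not called. Of 24 root and vascular regulators 20 rose and 4 fell, 24 when adjusted over the list alone (median 2.36; camera adjusted p = 1.2e-04, adjusted p = 0.168 with an estimated correlation). WOX5 rose from 0.893 ± 0.988 to 40.4 ± 7.14 TPM, JKD from 0.241 ± 0.0625 to 26 ± 4.91 TPM and MP (AT1G19850), the auxin response factor of the embryo axis, from 76.3 ± 23.5 to 372 ± 105 TPM. PLT2 (AT1G51190) fell from 135 ± 96.5 to 31.4 ± 9.63 TPM and the cytokinin response regulator ARR15 (AT1G74890) from 36.6 ± 7.26 to 3.25 ± 0.244 TPM. Of 14 tested zygote regulators 3 rose and 6 fell, 9 when adjusted over the list alone (median -0.52; camera adjusted p = 0.0101, adjusted p = 0.12 with an estimated correlation). Under median-ratio scaling 2 rose and 7 fell (median -0.93), and under quantile normalization 1 rose and 7 fell (-0.88). WOX8 fell from 27.9 ± 8.45 to 1.71 ± 1.23 TPM, WOX2 from 137 ± 10.9 to 19.3 ± 3.76 TPM and RKD2 (AT1G74480) from 8.84 ± 2.9 to 1.73 ± 0.875 TPM. EC1.4 (AT4G39340), of a family active in the egg cell, was listed at 0 in all 3 2/4-cell libraries and stood at 11.3 ± 7.61 TPM at heart (adjusted p = 0.00167). With library weights 15 shoot regulators rose and 1 fell, 8 polarity regulators rose, 18 root regulators rose and 4 fell, and 3 zygote regulators rose and 5 fell.

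Of 22 protoderm and cuticle genes 14 rose and 3 fell, 17 when adjusted over the list alone, and the list did not pass (adjusted p = 0.253). Under median-ratio scaling 7 rose and 4 fell (median 0.52 against 0.96), and under quantile normalization 8 rose and 4 fell (0.43). The cutin gene LACS2 (AT1G49430) rose from 7.97 ± 5.31 to 123 ± 9.06 TPM, the wax gene CER6 (AT1G68530) from 4.05 ± 4.88 to 39.4 ± 1.33 TPM and PDF1 from 376 ± 82.1 to 2197 ± 61.2 TPM. LTP1 (AT2G38540) and GPAT8 (AT4G00400) fell 24- and 9.97-fold. The protoderm regulator ATML1 (AT4G21750) stood at 88.9 ± 22 and 71.1 ± 10.9 TPM and was not called. Of 36 auxin genes 19 rose and 4 fell, 26 when adjusted over the list alone (camera adjusted p = 0.0367, adjusted p = 0.53 with an estimated correlation). LAX2 rose from 2.49 ± 1.05 to 63.8 ± 11.3 TPM and IAA20 (AT2G46990) from 0.233 ± 0.153 to 20.6 ± 5.97 TPM. The call of this list was lost without 2/4-cell replicate 1 (adjusted p = 0.0509) or 2/4-cell replicate 3 (0.0817). Of 23 maturation and seed storage genes 8 were tested, 5 rose and 2 fell, 7 when adjusted over the list alone, and the list did not pass (adjusted p = 0.373). The maturation regulators FUS3 (AT3G26790) and ABI3 (AT3G24650) rose from 5.53 ± 5.94 to 71.6 ± 1.76 TPM and from 11.5 ± 8.22 to 148 ± 21.6 TPM. LEC2 (AT1G28300) fell from 79.7 ± 21.3 to 22.9 ± 1.49 TPM, and LEC1 (AT1G21970) stood at 391 ± 149.6 and 512 ± 26.2 TPM and was not called. With library weights 12 protoderm, 18 auxin and 5 maturation genes rose, and 3, 4 and 2 fell.

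Most nuclear photosynthesis and fatty acid genes rose. Of 46 nuclear photosynthesis genes 45 rose and 1 fell, 46 when adjusted over the list alone (median 3.58; camera adjusted p = 2.0e-13, adjusted p = 0.259 with an estimated correlation). The light-harvesting gene LHCA1 (AT3G54890) rose from 9.66 ± 9.37 to 245 ± 23.9 TPM and LHCB5 (AT4G10340) from 13.3 ± 9.5 to 284 ± 24 TPM. The member that fell, the Rubisco small subunit gene RBCS3B (AT5G38410), lost its call without 2/4-cell replicates 2 or 3 or heart replicates 2 or 3 (adjusted p up to 0.105) and with library weights (0.0658). Of 28 fatty acid genes 24 rose and 0 fell, also 24 when adjusted over the list alone (median 1.52; camera adjusted p = 4.3e-06, adjusted p = 0.24 with an estimated correlation). Under median-ratio scaling 19 rose and 3 fell. ACP5 (AT5G27200) rose from 4.14 ± 2.29 to 67.4 ± 12.7 TPM and the desaturase gene FAD3 (AT2G29980) from 2.39 ± 2.94 to 29 ± 3.02 TPM. ACP3 (AT1G54630) stood at 472 ± 63.3 and 465 ± 56.3 TPM and was not called. Of 87 plastid-encoded genes 46 rose and 4 fell, 53 when adjusted over the list alone (median 1.80; camera adjusted p = 0.0367, adjusted p = 0.808 with an estimated correlation). Under median-ratio scaling 37 rose and 7 fell. That list's call was lost without 2/4-cell replicate 1 (adjusted p = 0.301), 2/4-cell replicate 3 (0.0596), 16-cell replicate 3 (0.0626) or heart replicate 1 (0.348), and its summed TPM was 7753 ± 3105 at 2/4-cell and 7203 ± 3146 at heart (exact permutation p = 1). With library weights 29 plastid-encoded genes rose and 4 fell, and 45 nuclear photosynthesis and 22 fatty acid genes rose.

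The sign of the median depended on the scaling for cell cycle, ribosomal, proteasome and histone genes. Of 51 cell cycle genes 13 rose and 3 fell, 12 when adjusted over the list alone. Their median was 0.17, of opposite sign to the test (adjusted p = 0.701), and turned to -0.28 under median-ratio scaling, where 8 rose and 15 fell, and to -0.07 under quantile normalization. CYCD3;1 (AT4G34160) rose from 5.87 ± 3.29 to 58.9 ± 6.86 TPM, KRP4 (AT2G32710), an inhibitor of cyclin-dependent kinases, from 11.7 ± 5.27 to 38.1 ± 1.64 TPM. CYCD3;2 (AT5G67260) stood at 351 ± 63.1 and 390.2 ± 11.1 TPM and was not called. Of 39 DNA methylation, small RNA and Polycomb genes 19 rose and 6 fell, 26 when adjusted over the list alone (median 0.79, 0.31 under median-ratio scaling and 0.45 under quantile normalization; adjusted p = 0.192). The chromomethylase gene CMT2 (AT4G19020) rose from 0.535 ± 0.173 to 31.4 ± 6.43 TPM, the demethylase gene ROS1 (AT2G36490) from 2.45 ± 1.18 to 35 ± 10.6 TPM and the methyltransferase gene DRM2 (AT5G14620) from 10.7 ± 2.76 to 64.1 ± 7.73 TPM. DRM1 (AT5G15380) fell from 33.5 ± 17 to 4.67 ± 1.79 TPM. Of 21 ribosomal protein genes 0 rose and 4 fell, 3 when adjusted over the list alone (camera adjusted p = 0.00363, adjusted p = 0.425 with an estimated correlation). Their median was -0.18 and turned to 0.14 under quantile normalization, where 4 rose and 1 fell, while under median-ratio scaling it was -0.67, with 0 rising and 14 falling. RPL10B (AT1G26910) fell from 104 ± 16.1 to 58.6 ± 4.43 TPM. Of 31 26S proteasome genes 8 rose, 6 when adjusted over the list alone (adjusted p = 0.319). Their median was 0.34 and turned to -0.15 under median-ratio scaling, where 1 rose and 4 fell, while under quantile normalization it was 0.29, with 7 rising and 1 falling. PAE1 (AT1G53850) rose from 186 ± 23.3 to 342 ± 12.8 TPM. Of 13 histone H3.1 and H4 genes 1, H4a (AT1G07660), rose, from 126 ± 18.4 to 200 ± 9.1 TPM, also 1 when adjusted over the list alone. It was not called under median-ratio scaling (adjusted p = 0.580), where the median of 0.04 turned to -0.45. The test had the opposite sign to the median of 0.04 (adjusted p = 0.424), which was 0.20 under quantile normalization. With library weights 12 cell cycle genes rose and 2 fell, 19 methylation, small RNA and Polycomb genes rose and 5 fell, 2 ribosomal genes fell, and 6 proteasome genes and 1 histone gene rose.

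Most heat shock and wounding genes fell over the course, and most seed coat markers were lower at heart than at 2/4-cell but not than at 8-cell. Of 21 seed coat markers 13 fell and 4 rose, 17 when adjusted over the list alone (median -1.58; camera adjusted p = 1.3e-05, adjusted p = 0.191 with an estimated correlation). TT3 fell from 168 ± 132 to 2.48 ± 1.78 TPM and LDOX (AT4G22880) from 62.2 ± 33.6 to 0.88 ± 1.01 TPM. The members that rose, named after their values were seen, were ATS (AT5G42630) (4.15 ± 2.91 to 36.5 ± 3.88 TPM), GATL5 (AT1G02720) (3.31 ± 4.59 to 21.9 ± 3.77), SBT1.7 (AT5G67360) (26.3 ± 11.2 to 66.8 ± 6.21) and PER36 (AT3G50990) (0.047 ± 0.0814 to 2.83 ± 2.3). Summed over 24 seed coat markers, the level was 1126 ± 596 TPM at 2/4-cell (522 to 1714 in its libraries), 124 ± 41.4 at 8-cell, 95.3 ± 7.79 at 16-cell, 273 ± 138 at 32-cell, 219.7 ± 10.2 at globular and 229.9 ± 2.24 at heart. The exact permutation p between the first and last stage was 0.1, two-sided and the smallest that 3 against 3 libraries allow. Of 17 endosperm markers 3 were tested and 0 called, also 0 when adjusted over the list alone (adjusted p = 0.282). Their sum was 67.7 ± 67.9 TPM at 2/4-cell, 145.9 in replicate 3, and 23.5 ± 1.7 at heart (exact permutation p = 0.3). Of 17 heat shock and wounding genes 16 fell and 0 rose, also 16 when adjusted over the list alone (median -4.26; camera adjusted p = 5.9e-16, adjusted p = 0.119 with an estimated correlation). The small heat shock genes HSP17.4 (AT3G46230), HSP23.6 (AT4G25200) and HSP17.6A (AT5G12030) fell from 176 ± 21.5 to 3.38 ± 2.15 TPM, from 103 ± 38.5 to 1.85 ± 1.34 TPM and from 176 ± 80 to 4.1 ± 2.34 TPM. Of 30 mitochondrion-encoded genes 14 fell and 3 rose, 17 when adjusted over the list alone (median -1.68; camera adjusted p = 1.3e-05, adjusted p = 0.191 with an estimated correlation). Their sum was 14138 ± 5815 TPM at 2/4-cell, 7436 to 17841 in its libraries, and 2886 ± 1336 at heart (exact permutation p = 0.1). How the poly(A) capture bore on organelle genes was not tested. With library weights 13 seed coat markers fell and 4 rose, 14 heat shock and wounding genes fell, and 13 mitochondrion-encoded genes fell and 1 rose.

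**Figure D4:**
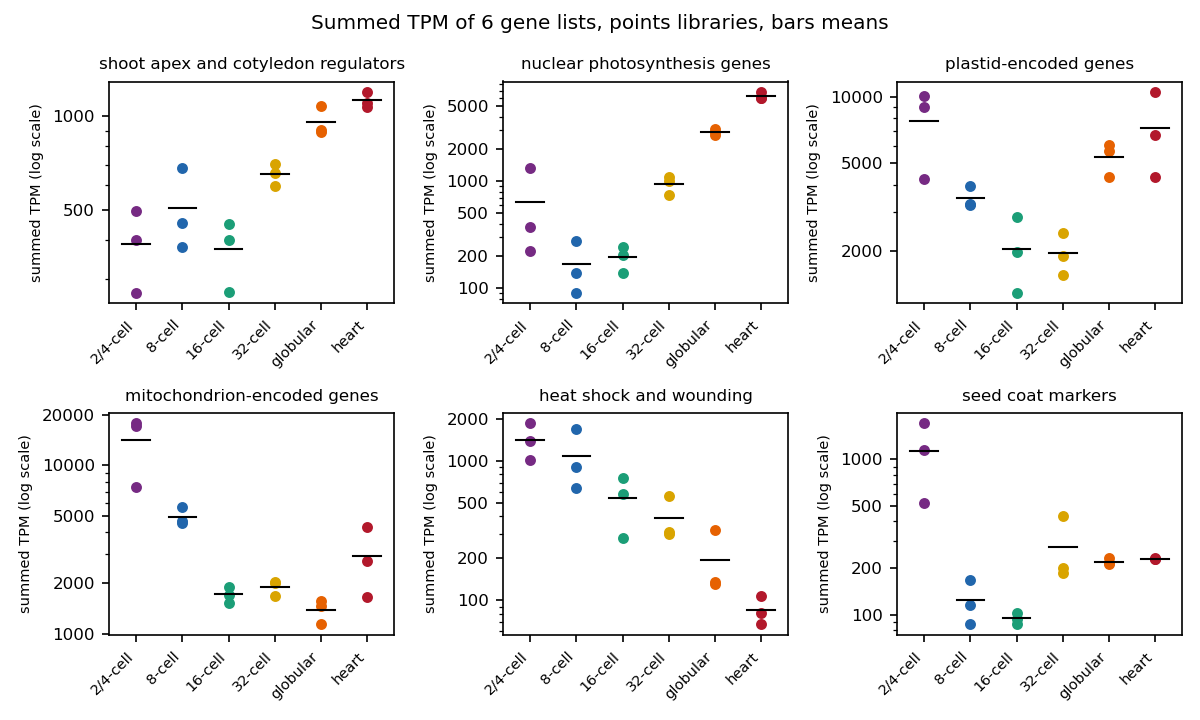
Summed TPM (y axes, log scale) of 6 gene lists in each library (points) at the 6 stages (x axes), with bars at the means of 3 libraries. Nuclear photosynthesis genes reach 6279 ± 505 TPM at heart, heat shock and wounding genes go from 1426 ± 431 to 85 ± 20 TPM, and seed coat markers stand at 522 to 1714 TPM in the 2/4-cell libraries against 433 or less in the others.

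Limma called 8596 genes between the 2/4-cell and heart stages, 6335 higher (73.7%) and 2261 lower at heart, and library weights 7193, with 7154 called by both. Under median-ratio scaling 49.5% of the calls were higher and under quantile normalization 52.8%, and these kept 5980 and 5901 of the 8596 calls with 0 reversed. Against the 8-cell stage in place of the 2/4-cell stage, an alternative chosen after the data were seen, 6579 genes differed, 77.2% of them higher at heart, and 1168 of the 2261 lower genes were lower in both. In that comparison seed coat markers had 7 members higher and 2 lower (median 0.15, adjusted p = 0.659), heat shock and wounding genes 14 lower (median -3.05), and nuclear photosynthesis genes 46 higher (median 4.4). In 9721 genes (53.0%) the libraries of the first and last stage did not overlap, where exchangeable libraries give 10%.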

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

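The tests of heart against 8-cell, of the F test without the 2/4-cell stage and of the length trend, and the splits of the libraries, were chosen after the results were seen. Of 157 results for named genes, each for 1 gene in 1 comparison, 103 kept their direction and their side of the threshold under every alternative run on them, and 0 reversed. Of 61 list calls 2 did so. Removal of the length trend and heart against 8-cell are not among these alternatives. Nor do the 157 results cover every gene named in the text, PLT1, LEC1 and CYCD3;2 being among those left out. Many of the 157 were picked by the rule for large changes without overlap, so a reversal was unlikely from the start. The counts of called genes moved by over 1.5 times under the settings that follow, and the cause was not tested except that some settings use fewer libraries or other genes. Library weights gave 592 genes for 8-cell against 2/4-cell, 3465 for globular against 32-cell and 2005 for heart against globular. With only the stages compared in the limma fit, 67 genes were called for 8-cell against 2/4-cell, 0 for 16-cell against 8-cell (1675 at an unadjusted p under 0.05), 659 for 32-cell against 16-cell and 1501 for globular against 32-cell. Without a filter 170 were called for 16-cell against 8-cell and 219 for heart against globular. Quantile normalization gave 736 for 32-cell against 16-cell. For heart against globular pseudocounts of 0.1 and 5 gave 47 and 169, and a filter of 5 TPM gave 62.

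With 1 library left out, the counts ran from 954 (without 8-cell replicate 1) to 2333 (2/4-cell replicate 1) for 8-cell against 2/4-cell, from 108 (16-cell replicate 2) to 427 (2/4-cell replicate 1) for 16-cell against 8-cell, and from 550 (32-cell replicate 1) to 1432 (2/4-cell replicate 1) for 32-cell against 16-cell. They ran from 131 (globular replicate 2) to 496 (2/4-cell replicate 3) for globular against 32-cell, from 31 (globular replicate 3) to 128 (2/4-cell replicate 3) for heart against globular, from 6911 (heart replicate 1) to 9067 (16-cell replicate 3) for heart against 2/4-cell, and from 7700 (heart replicate 1) to 9718 (2/4-cell replicate 1) for the F test. A block for the replicate number gave 1590, 286, 1123, 406, 100 and 8742 genes in the order of the comparisons, heart against 2/4-cell last, and 9176 in the F test.

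The direction of 3 list results reversed under another filter or scaling, and the cause was not tested. Fry asks another question than camera, since it tests a list against no change. With it cell cycle genes (median log2 change 0.0443, adjusted p = 0.864) and plastid-encoded genes (0.10, 0.821) in 32-cell against 16-cell had the sign of their median, while camera set them below all genes, whose median was 0.24. With a filter of 5 TPM maturation genes in heart against globular had a median of 0.0348 (0.965). With quantile normalization cytosolic ribosomal proteins had a median of 0.00252 in heart against globular (0.952) and 0.14 in heart against 2/4-cell (0.366). The 6 libraries of a comparison make 10 splits, too few for a share under 0.05: the real split gave the most calls, 1 of 10, and the highest other counts were 24, 4, 1, 0, 3 and 0. For the F test 1 of 100 splits, the real one with 9003 genes, gave as many, and the highest other gave 613. That share of 0.01 is the smallest these splits can give, so chance is not excluded. A split that mixes stages puts any stage difference into the spread, which lowers its calls. The counts of the other splits therefore do not measure false calls. Without depths, no limit for low values was derived.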

Other observations

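The tests of the sulfur limitation list, of the small cysteine-rich genes and of the scaling were chosen after results were seen, and the pollen and clock lists were written after the changes that prompted them were seen. The tests without members already seen were added later still. Of 13 listed sulfur limitation genes 12 were tested, and between the 2/4-cell and heart stages 11 rose and 1 fell (median log2 change 3.98, camera adjusted p = 1.3e-06, adjusted p = 0.0448 with an estimated correlation). AT5G26220, listed as GGCT2;1, stood at 6.52 ± 4.43 TPM at 2/4-cell, 25.6 ± 12.9 at 32-cell, 404 ± 80.8 at globular and 894 ± 71.8 at heart. APR2 (AT1G62180), of sulfate reduction, stood at 18 ± 1.4 and 241 ± 31.4 TPM at the first and last stage, LSU2 (AT5G24660) at 10.1 ± 3.71 and 112 ± 23.8, and the member that fell, SULTR2;1 (AT5G10180), at 6.34 ± 7.74 and 0.0822 ± 0.0572. From 32-cell to globular 7 rose and 0 fell (median 2.01, adjusted p = 2.0e-15, adjusted p = 0.00483 with an estimated correlation). ATSDI1, LSU1 and SULTR1;2 had been seen before the list was written. Without them the adjusted p with an estimated correlation was 0.0951 between 2/4-cell and heart, where 8 rose and 1 fell, and 0.0374 from 32-cell to globular, where 4 rose.

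Of 107 small cysteine-rich genes of the LCR and SCRL families measured, 40 were tested and 22 varied over the stages. Of these 10 had their highest mean log2(TPM + 1) at 32-cell and 6 at 2/4-cell. LCR48 (AT3G48231) stood at 172 ± 128 TPM at 2/4-cell, 634 ± 144 at 16-cell, 2309 ± 476 at 32-cell and 51.7 ± 27.6 at heart. From 32-cell to globular 7 fell and 0 rose (median -1.15, camera adjusted p = 3.2e-14, adjusted p = 0.0183 with an estimated correlation). LCR22, LCR23, LCR35, LCR36, LCR48, LCR68 and SCRL26, had been seen before this list was written. Without these 7 genes 1 fell (median -0.92, adjusted p = 1.0e-07), and with an estimated correlation the list was not called (adjusted p = 0.0663).

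Seed coat markers were higher at the 2/4-cell stage, and RNA of seed coat cells in those libraries may explain it. Markers of 1 source keep 1 ratio, and 57.1% of the 21 tested markers ordered the 3 libraries of the 2/4-cell stage as their sum did. The share was also 57.1% with each marker left out of the sum it was compared with, a test added later. Of all tested genes 16.8% had that order. The order was not specific to seed coat markers and does not single out this source, since 63.0% of nuclear photosynthesis genes, 58.8% of heat shock and wounding genes and 69.2% of histone genes shared it. Of the 24 markers 15 had a mean of 1 TPM or more at 8-cell and 15 at heart, and 0 are in another list. The labels name manual isolation and no sort that would remove such cells. A change in the embryos themselves stays open and was not tested.

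RALF-like genes and AGP23 were also higher at the 2/4-cell stage, and RNA of pollen or pollen tubes is a candidate source. The median of 25 pollen markers there was 2.19 TPM, 1.63% of the median of 134 TPM of the 5 named genes, between the bounds set beforehand, so this source cannot be told apart from expression in the embryo. The 5 genes had been picked from these same data for large falls from 2/4-cell and a mean of 10 TPM or more, which lowers this ratio. Of the 25 pollen markers 18 had a mean of 1 TPM or more at 2/4-cell, 6 at 8-cell and 8 at heart, and 0 are in another list. The most abundant were AGP11 (AT3G01700) at 52 ± 42.1 TPM and AGP40 (AT3G20865) at 39.2 ± 25.3 TPM, while PPME1 (AT1G69940) was listed at 0. From 2/4-cell to 8-cell 7 of 14 tested on this list, outside the fixed ones, fell (median -1.64, camera adjusted p = 5.5e-09, adjusted p = 0.0656 with an estimated correlation).

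More genes were higher than lower at heart than at 2/4-cell, 73.7% of the calls, and whether the scaling of each library to a fixed total accounts for the excess stays open. Under median-ratio scaling the share was 49.5%, but that scaling centres the libraries and largely fixes the share, so the scaling and a change in the embryos cannot be told apart. A trend with transcript length stays open as well. Across genes, the log2 change from 2/4-cell to heart had a Spearman's rho of 0.263 with length. For a library's deviation from the mean of its own stage, rho ran from -0.480 in 16-cell replicate 3 to 0.438 in heart replicate 1. The latter describes spread between replicates and not a difference between stages. With the length trend removed from each library, 66.4% of the called genes were still called with the same sign, 5666 of 8529. This lay between the bounds set beforehand, and 46.7% of the calls were higher. The removal also centres each library, so the trend and the scaling cannot be told apart for the calls it ended. The trend itself had been seen before its test was written.

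LHY was higher at 32-cell than at 16-cell, and collection at another time of day may explain it. The median log2 change of 7 morning clock genes exceeded that of 7 evening clock genes by 1.45. Of the morning genes, LHY among them, 5 rose (median 1.59, camera adjusted p = 5.5e-09, adjusted p = 0.00483 with an estimated correlation), with CCA1 (AT2G46830) at 3.04 ± 1.46 TPM at 16-cell and 19.2 ± 3.51 at 32-cell. Without LHY, seen before the list was written, 4 of 6 rose (median 1.28, adjusted p = 2.5e-06, adjusted p = 0.00832 with an estimated correlation). Of the evening genes 0 rose and 1 fell (median 0.14, of opposite sign to the test, adjusted p = 0.0520). From 8-cell to 16-cell 1 morning gene fell (median -0.73, adjusted p = 2.1e-04, adjusted p = 0.0294 with an estimated correlation), and without LHY the latter was 0.0663. After 32-cell the morning genes stayed up, with medians of 0.16 from 32-cell to globular and 0.28 from globular to heart and 0 called. From 2/4-cell to heart 6 of them rose and 0 fell (median 2.07). The time of day explanation had evening genes falling. Their median from 16-cell to 32-cell did not fall, but it lay below the median of 0.24 over all tested genes. The labels give no collection time for any stage, so these values do not decide. A start of clock gene expression in the embryo stays open and was not tested.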
